A study of Mus musculus with 9 samples.

How the data were processed

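RNA was sequenced from 9 libraries of mouse CD8 T cells in 3 groups of 3: wild type (WT), a group whose genotype label names CTCF loss (CTCF KO), and a group whose genotype label names loss of both Tcf1, the product of Tcf7, and Lef1 (DKO). The donors carried a Cre recombinase under human CD2 control (hCD2-Cre) and a GFP reporter in Rosa26 that Cre switches on, with floxed target alleles in the knockout groups. Naive CD8 T cells were stained with CTV, a dye that dividing cells dilute, and placed in Rag1-deficient hosts, which have no B or T cells of their own. After 72 h, cells positive for CTV, GFP, TCRβ and CD8 were sorted from the spleen. The source names also read "stim CD8", and the labels describe no other stimulus. Total RNA was taken on RNeasy columns and sequenced on the Illumina Hiseq-2000 platform.

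The authors deposited a table of 23946 genes that holds FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) for each library and the mean FPKM of each group. The same deposited table holds the p-values and q-values (FDR) of the authors' comparisons of the groups, made pair by pair. The processing notes name FastQC, TopHat2 2.1.0 and Cuffdiff 2.2.1, and both the mm9 and the mm10 genome builds; the library scaling, annotation and filters are not stated. Among 22463 genes matched by symbol, 962 had a start within 1000 bases of the GRCm38 (mm10) start, so the positions printed here are not on GRCm38, and mm9 is the other build that the notes name. The deposited group means equalled the mean of the 3 library columns within 1% for 23941 genes in CTCF KO, 23941 in DKO and 23927 in WT. The log2 fold change columns of the table were not used, because they hold error entries where a mean is 0. The table gives no counts, so the depth of each library is unknown and no counting error is given. The DKO libraries are numbered differently in different labels, so their columns were tied to the group only.

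Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, which left 10172 genes. Values were taken as log2(FPKM + 1), and every log2 fold change is on this scale, which understates the fold of genes with low FPKM. A linear model with 1 mean per group was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes moderation with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison. A gene was called at an adjusted p under 0.05. All adjusted p-values for genes are from this limma model unless they are said to be the authors' q-values, and the tests are two-sided. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries.

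Before the data were examined, 30 gene lists, the comparisons, the tests, the alternatives and the rule for naming genes were fixed. The programme lists were T cell identity, naive and quiescence, cytotoxic effector, homeostatic cytokine response, T cell receptor signalling and immediate early, inhibitory receptors and exhaustion, trafficking receptors, non-CD8 T lineage genes, G1/S and S phase, G2/M and mitosis, replication-dependent histones, cohesin and loop factors, imprinted genes, interferon-stimulated genes, p53 targets and apoptosis, ribosome biogenesis, oxidative phosphorylation, glycolysis, cholesterol synthesis, and the 3 targeted genes. The lists for other cells were B cell, plasma cell, NK cell, neutrophil, macrophage and monocyte, dendritic cell, erythroid, platelet and megakaryocyte, and stroma and endothelium markers. The mitochondrially encoded list had 0 members in the table. Of 711 listed genes, 679 were matched, 7 of them by an older symbol. Each of the 26 lists with at least 3 tested members was tested with camera, which asks whether its members moved more in one direction than the other tested genes, with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. The camera p-values were adjusted over the 26 lists. For each list, the genes were also counted with p-values adjusted over the list alone.

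Genes were named by a fixed rule. Ctcf, Tcf7 and Lef1 were always named. For each comparison, the rule took the 10 called genes with the largest rise and the 10 with the largest fall that had a mean of at least 5 FPKM in the higher group and no overlap between the libraries of the groups. Predicted genes, small RNAs and antigen receptor segments were left out of these. From each list it took up to 4 called members with the smallest adjusted p, or up to 2 members with the highest mean where none was called, and from the overlap of both knockouts 5 genes per direction. Names outside the rule are said to have been chosen after their values were seen.

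For genes called in both knockouts, the count for independent lists was computed from the called totals. In 100 simulations, groups with no difference were drawn with the observed spread and 1 shared WT group, to give the correlation and covariance that shared controls alone produce. The spread between libraries was also related to base composition. For each gene, 1 reference transcript was used, the longest protein-coding one or, where none was protein-coding, the longest. The highest GC content of any 100-nt window (step 25 nt) of this transcript was computed, with a value for 10110 of the tested genes (99.4%). A library index was the median deviation of genes with a window of at least 80% GC minus that of genes whose windows were all under 70%.

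The alternatives were a pseudocount of 0.1 FPKM, no filter, a mean of at least 5 FPKM, quantile normalization, a common library median, no intensity trend, array weights, a fit to only the compared groups, a minimum of 1.5-fold, a block on the replicate number in a fit to only the CTCF KO and WT libraries, leaving out each replicate, Spearman in place of Pearson correlation, an estimated inter-gene correlation, and fry. Another 3 were added after the data had been seen: leaving out CTCF KO library 1 and WT library 3 together, testing only genes with no window of 70% GC or more, and using the library index as a covariate. The method was tested on simulated data with 200 changed genes per size of change. It recovered 38.5% to 47.5% of 1.5-fold changes, 78.0% to 83.0% of 2-fold changes and 96.0% to 97.0% of 4-fold changes, with at most 5.88% false calls. In the simulated lists of 30 genes, camera called the 1 list shifted by 0.5 log2 and 0 of the 28 others. The simulated noise was independent between genes, with no deviation shared across the genes of a library. The rates of false calls for genes and lists may therefore be higher in the real libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.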

Results

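Gene expression was measured by RNA sequencing in CD8 T cells recovered after 72 h in lymphocyte-deficient hosts; how far they had divided was not measured. There were 3 libraries each of WT, CTCF KO and DKO cells, 9 in all. Values are FPKM as mean ± SD over the 3 libraries of a group. The depth of each library is unknown, because the values are FPKM only. The summed FPKM of a library lay between 629663 and 702470, and 9613 to 9832 genes reached at least 1 FPKM. The gene with the highest FPKM in every library was Tmsb4x, which encodes an actin-binding peptide, and the 10 highest genes made up 7.32% to 7.80% of the sum. Pearson correlations between libraries were 0.960 to 0.992 within groups and 0.899 to 0.978 between groups.

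The targeted genes were examined first. Ctcf, which encodes a zinc finger protein that anchors chromatin loops, had 18.3 ± 1.64 FPKM in the libraries labelled CTCF KO (20.2, 17.1 and 17.6) and 23.9 ± 7.7 in WT (18.6, 20.3 and 32.7). Its log2 fold change of -0.33 (SE 0.19, adjusted p = 0.319) did not pass the test, and the authors' q-value was 0.109. Ctcf RNA was therefore not called lower, and every direction given for this group is that of the libraries labelled CTCF KO. In DKO libraries Ctcf had 35.7 ± 3.36 FPKM, above WT by 0.60 (adjusted p = 0.0293). Ctcf has a transcript window of 86% GC, and with the GC index as a covariate this difference was 0.01 (adjusted p = 0.977). The lowest index of a DKO library (0.324) lies above the highest of the other libraries (0.127). In comparisons with DKO the covariate can therefore also take up an effect of genotype, and does not separate it from recovery of GC-rich windows. Lef1 fell to 90.7 ± 4.41 FPKM in DKO from 346 ± 12.4 in WT (log2 fold change -1.92, adjusted p = 1.4e-08). Tcf7 RNA was higher in DKO, at 342 ± 11.3 against 257 ± 6.43 (log2 fold change 0.42, adjusted p = 0.000223). Tcf7 RNA was therefore not lower in DKO and Lef1 RNA was still present, so what is given for this group holds for the libraries labelled DKO, and these values do not show the loss of Tcf7. In the libraries labelled CTCF KO, Lef1 had 431 ± 2.54 FPKM (log2 fold change 0.32, adjusted p = 0.00397) and Tcf7 265 ± 11.5 (adjusted p = 0.666). Ctcf lies on chromosome 8 (108160438 to 108206822), Tcf7 on chromosome 11 (52066106 to 52095752) and Lef1 on chromosome 3 (130813215 to 130927275). Of the 3 targeted genes as a list, 1 rose in CTCF KO against WT (1 adjusted over the list alone; camera adjusted p = 0.441). In DKO against WT, 2 rose and 1 fell (the same adjusted over the list alone), and the median of 0.42 and the upward test (adjusted p = 0.905) differed in sign from the mean of -0.30.

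**Figure D1:**
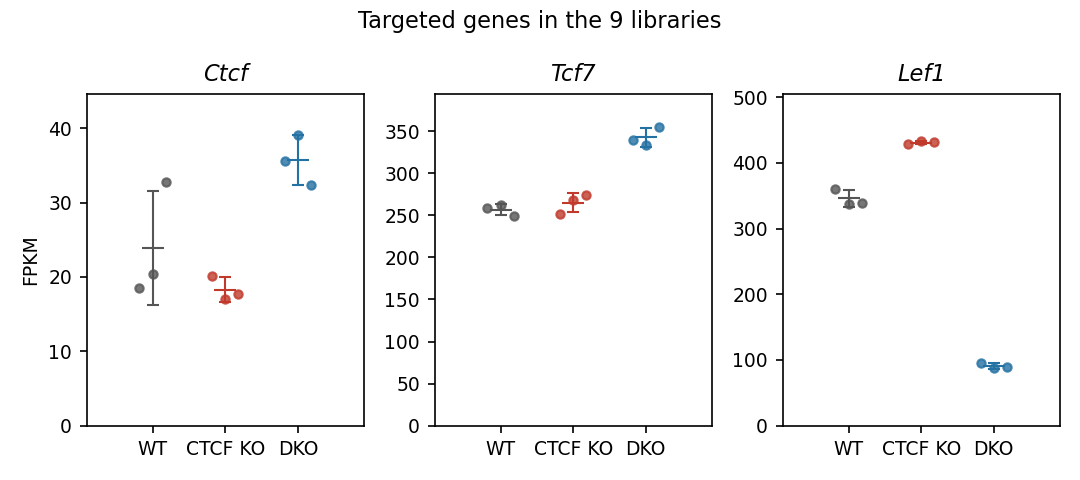
FPKM of Ctcf, Tcf7 and Lef1 in each of the 9 libraries (points), with the mean (horizontal bar) and SD (error bars) of the 3 libraries of WT, CTCF KO and DKO on linear axes from 0. Ctcf spans 18.6 to 32.7 FPKM in WT and 17.1 to 20.2 in CTCF KO, whereas Lef1 has a mean of 90.7 FPKM in DKO and 346 in WT.

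To ask which transcripts differ where CTCF was targeted, the libraries labelled CTCF KO were compared with WT. Mitotic transcripts and effector transcripts of CD8 T cells were lower in them. Gzmm, which encodes a granzyme, fell from 39.5 ± 1.73 to 2.15 ± 0.216 FPKM, the chemokine receptor Cxcr3 from 92.8 ± 6.16 to 20.2 ± 1.26, and the cytokine Ifng from 11.4 ± 0.821 to 2.15 ± 0.544. Birc5, which encodes survivin, a protein of the mitotic chromosomal passenger complex, fell from 246 ± 1.1 to 93.6 ± 5.12 FPKM. Cd247, the ζ chain of the T cell receptor complex, rose from 359 ± 29.1 to 1157 ± 31.4. In all, 588 genes were higher and 648 lower, 12.2% of the 10172 tested. At 1.5-fold or more there were 249 and 358, and at 2-fold or more 77 and 172. The libraries of both groups did not overlap for 30.4% of genes, where chance gives 10%. The authors' q-values under 0.05 marked 433 genes higher and 578 lower, and 755 genes were called by both in the same direction, with 0 in opposite directions.

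Cytotoxic effector genes fell together: of 27 tested, 0 rose and 12 fell (1 and 15 adjusted over the list alone). Their mean log2 fold change was -0.90 (camera adjusted p = 2.5e-12, and adjusted p = 0.00221 with an estimated correlation). Besides Gzmm, the called members with the smallest adjusted p were Ccl5, a chemokine (75.7 ± 8.31 FPKM against 278 ± 18.5), Tbx21, which encodes the transcription factor T-bet (8.45 ± 0.854 against 30.9 ± 1.05), and Gzma, another granzyme (9.07 ± 0.0659 against 26 ± 1.63). Gzmb was not called, at 50.6 ± 1.58 against 58.2 ± 5.55 FPKM (adjusted p = 0.138). NK cell markers also moved down, with 2 of 9 lower, Klre1 and Klra9 (0 and 4 adjusted over the list alone; adjusted p = 0.00409, and adjusted p = 0.188 with an estimated correlation). Their call was lost with a mean of at least 5 FPKM. Neutrophil markers moved with these groups: 6 of 7 fell (0 and 7 adjusted over the list alone; adjusted p = 2.4e-07, and adjusted p = 0.0112 with an estimated correlation). Among them Ngp, a granule protein, had 0.269 ± 0.466 FPKM against 6.85 ± 1.3, and S100a8, a calcium-binding protein, 10.04 ± 0.507 against 22.8 ± 2.5. Some members of this list were low even in WT, with Lcn2 at 1.30 to 2.46 FPKM and Ltf at 1.74 to 2.40.

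Cell cycle lists fell as well. Of 36 G2/M and mitosis genes, 0 rose and 35 fell (0 and 36 adjusted over the list alone), with a mean log2 fold change of -1.20 (adjusted p = 6.3e-39, and adjusted p = 0.000756 with an estimated correlation). Cdc20, which activates the anaphase-promoting complex, had 54 ± 3.81 FPKM against 134 ± 10.1, and Ube2c, its ubiquitin-conjugating enzyme, 54.5 ± 4.84 against 176 ± 14.7. Of 36 G1/S and S phase genes, 0 rose and 12 fell (1 and 15 adjusted over the list alone; adjusted p = 3.1e-08, but adjusted p = 0.0521 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell from 302 ± 17.7 to 124 ± 4.79 FPKM, and Tyms, thymidylate synthase, from 32.9 ± 1.17 to 18.6 ± 0.627. Of 17 replication-dependent histone genes, 4 fell (0 and 4 adjusted over the list alone; adjusted p = 0.00362, but adjusted p = 0.271 with an estimated correlation), and this call was lost with a mean of at least 5 FPKM or in genes without a GC-rich window. Of 24 cohesin and loop factors, 4 fell (1 and 4 adjusted over the list alone; adjusted p = 0.224). These were Espl1, Sgol1, Cdca5 and Esco2, which act on sister chromatids in S phase and mitosis.

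Among the largest rises were the Y-linked genes Ddx3y (35.6 ± 2.29 FPKM against 0.277 ± 0.204 in WT and 0.22 ± 0.149 in DKO), Eif2s3y, Uty and Kdm5d. Their summed FPKM was 90.0 to 100.9 in every library labelled CTCF KO and at most 2.03 in the other 6, and Xist, the RNA that coats the inactive X chromosome, was at most 0.00696 FPKM in the first and 1.71 to 2.48 in the second. Xist was chosen after its values were seen. BC018473 had 83.2 ± 2.62 FPKM against 0.0177 ± 0.0175, and St6galnac2, a sialyltransferase gene, 88.1 ± 3.19 against 0.407 ± 0.00943. Both lie on chromosome 11, from 116613481 to 116619197 and from 116538019 to 116555974. Jmjd6, which begins at 116698746 on the same chromosome and was chosen after its values were seen, had 62.6 ± 2.77 against 61.6 ± 4.74. Ephb6, an ephrin receptor gene beside the T cell receptor β locus, rose from 11.2 ± 1.77 to 79.1 ± 4.2 FPKM. F12, Rph3al and Cela2a complete the 10 largest rises. Cela2a, a pancreatic elastase gene, had 7.34 ± 0.208 FPKM, 0.944 ± 0.335 in DKO, and was listed at 0 in every WT library. Pnlip and Clps, also pancreatic and chosen after their values were seen, had 4.08 ± 0.266 and 5.28 ± 2.86 FPKM and were listed at 0 in WT. The largest falls besides Gzmm, Ngp, Klre1, Cxcr3 and Ifng were the natural killer receptor pseudogene Klra13-ps (2.79 ± 0.807 against 51.3 ± 3.07), Samd3, Xlr3b, Plek and Cd163l1.

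T cell identity genes moved up: 4 of 22 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.00934, but adjusted p = 0.444 with an estimated correlation). The risers included Cd247, Cd5 and Lat, all parts of T cell receptor signalling, and without WT library 3 the list was not called. Of 23 T cell receptor signalling and immediate early genes, 2 rose and 6 fell (2 and 6 adjusted over the list alone; adjusted p = 0.00676, but adjusted p = 0.212 with an estimated correlation). Tnfaip3, an inhibitor of NF-κB signalling, fell to 23.2 ± 1.98 from 45.4 ± 4.32 FPKM. This list's call was lost without WT library 3 (adjusted p = 0.0505), and in genes without a GC-rich window its direction turned up (adjusted p = 0.880). Cholesterol synthesis genes rose in 7 of 23 cases and fell in 0 (8 and 0 adjusted over the list alone; adjusted p = 0.00383, but adjusted p = 0.264 with an estimated correlation); Sqle, squalene epoxidase, had 20.8 ± 1.07 against 11.5 ± 2.53 FPKM. Of 35 interferon-stimulated genes, 2 rose and 6 fell (2 and 9 adjusted over the list alone; adjusted p = 0.00362, but adjusted p = 0.355 with an estimated correlation). Ifi27l2a fell from 888 ± 46.8 to 399 ± 11.7, while Irf7, an interferon regulatory factor, rose from 73.7 ± 6.08 to 111 ± 5.97. Of 41 oxidative phosphorylation genes, 0 rose and 7 fell (1 and 7 adjusted over the list alone; adjusted p = 0.00474, but adjusted p = 0.504 with an estimated correlation), and the call was also lost with quantile normalization, with fry, without CTCF KO library 1 or WT library 1, or in genes without a GC-rich window.

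The remaining programmes were not called as lists. In the homeostatic cytokine response, 7 of 25 rose and 4 fell (10 and 4 adjusted over the list alone; adjusted p = 0.137). Il2rb, the receptor chain shared by IL-2 and IL-15, fell from 192 ± 2.56 to 94.5 ± 4.56 FPKM, and Bcl2, which opposes apoptosis, rose from 96.8 ± 1.18 to 145 ± 10.01. Of 30 naive and quiescence genes, 4 rose and 4 fell (7 and 6 adjusted over the list alone; adjusted p = 0.579, upward like the median of 0.09, with a mean of -0.03). Slfn2 and Ly6c2 fell, and Igfbp4 rose from 217 ± 26.2 to 388 ± 19.8. Of 23 trafficking receptors, 4 rose and 7 fell (6 and 10 adjusted over the list alone; adjusted p = 0.118), with Ccr9 among the higher. p53 targets and apoptosis genes rose in 4 of 28 cases and fell in 2 (5 and 2 adjusted over the list alone; adjusted p = 0.219); Phlda3 rose from 1.65 ± 0.312 to 6.92 ± 0.953 and Bax, which promotes apoptosis, from 208 ± 8.8 to 282 ± 13.2. Inhibitory receptors and exhaustion genes split 1 higher (Tnfrsf18) and 1 lower (Cd200) of 16 (1 and 4 adjusted over the list alone; adjusted p = 0.224). Non-CD8 T lineage genes split 1 higher (Ccr4) and 2 lower (Cxcr5, Gata3) of 8 (1 and 3 adjusted over the list alone; adjusted p = 0.224). Glycolysis genes split 3 higher and 1 lower of 20 (3 and 1 adjusted over the list alone; adjusted p = 0.809, upward like the mean of 0.05, with a median of -0.01). Ribosome biogenesis genes split 1 and 1 of 39 (0 and 0 adjusted over the list alone; adjusted p = 0.579). Of 14 imprinted genes, 1 fell, Commd1 (0 and 1 adjusted over the list alone; adjusted p = 0.717, downward like the mean of -0.02, with a median of 0.01).

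Markers of other cells gave few calls outside the neutrophil and NK lists. B cell markers had 2 of 6 lower, Cd22 and Cd79b (0 and 2 adjusted over the list alone; adjusted p = 0.224, downward like the mean of -0.39, with a median of 0.03). Macrophage and monocyte markers had 1 higher (Apoe) and 1 lower (Lyz2) of 17 (1 and 1 adjusted over the list alone; adjusted p = 0.328). Dendritic cell markers had 1 higher (Ccr9) and 1 lower (Bst2) of 9 (1 and 3 adjusted over the list alone; adjusted p = 0.457). Of 9 erythroid markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone; adjusted p = 0.579). Plasma cell, platelet and megakaryocyte, and stroma and endothelium markers had 2 tested members each, too few for a list test, and only Pecam1 of the last list was called, higher at 41.2 ± 2.46 against 33.9 ± 0.447 FPKM (1 and 0 adjusted over the list alone).

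Leaving out a single library lowered the count of higher genes to 343 to 481 and of lower genes to 411 to 572. It fell by over 1.5 times without CTCF KO library 2 or 3 or WT library 2 or 3 for higher genes (346, 343, 352 and 381), and without WT library 2 for lower genes (411).

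**Figure D2:**
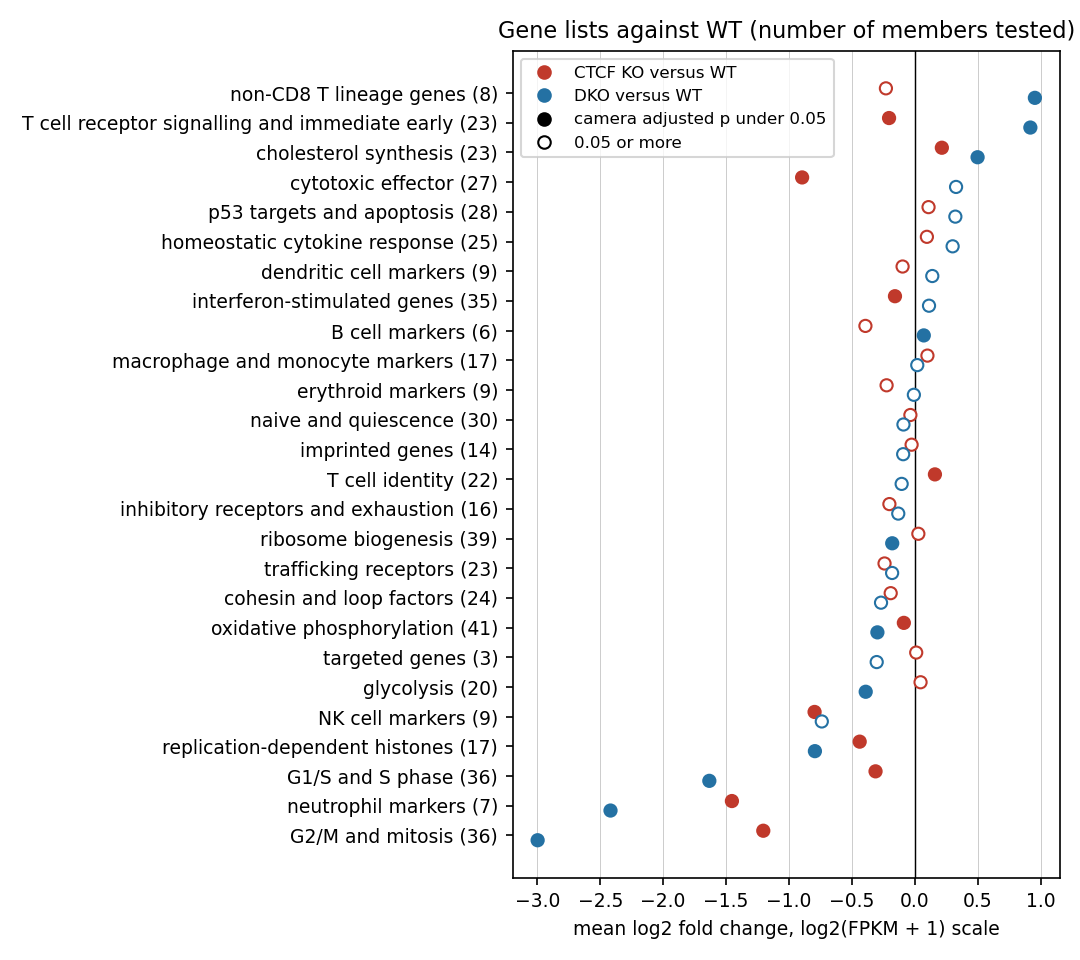
Mean log2 fold change of the tested members of 26 gene lists, on the log2(FPKM + 1) scale, in CTCF KO against WT (red) and DKO against WT (blue), with the number of members tested in parentheses. Filled points have a camera adjusted p under 0.05 with the preset correlation; the G2/M and mitosis list has a mean of -1.20 in CTCF KO and -3.00 in DKO, and the cytotoxic effector list -0.90 and 0.33.

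To ask which transcripts differ where Tcf7 and Lef1 were targeted, the libraries labelled DKO were compared with WT. Transcripts of the cell cycle were far lower in DKO, while several effector transcripts and the lineage regulators Foxp3 and Gata3 were higher. Foxp3, the transcription factor of regulatory T cells, rose from 0.877 ± 0.216 to 109 ± 5.84 FPKM, Gzma from 26 ± 1.63 to 709 ± 69.2, and Fasl, the death receptor ligand, from 5.74 ± 0.263 to 133 ± 6.64. Ly6c2, which encodes a Ly6C antigen, fell from 799 ± 101 to 19.5 ± 1.51 FPKM, and Dapl1 from 437 ± 40.4 to 22.7 ± 2.15. Of the 10172 tested genes, 1886 were higher and 2227 lower (40.4%), with 1054 and 1035 at 1.5-fold or more and 540 and 484 at 2-fold or more. The groups did not overlap for 54.1% of genes, where chance gives 10%. The authors' q-values under 0.05 marked 1638 genes higher and 1410 lower, and 2592 genes were called by both in the same direction and 0 in opposite directions.

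Cytotoxic effector genes went both ways: 13 of 27 rose and 9 fell (14 and 9 adjusted over the list alone; adjusted p = 0.226). Ccl5 rose from 278 ± 18.5 to 1471 ± 4.09 FPKM and Gzmb from 58.2 ± 5.55 to 547 ± 23.8, whereas Gzmm fell to 2.95 ± 0.708. NK cell markers had 1 higher (Nkg7) and 3 lower of 9 (1 and 4 adjusted over the list alone; adjusted p = 0.479), with Klre1 at 0.601 ± 0.261 FPKM against 9.35 ± 2.66. Neutrophil markers fell in 7 of 7 cases (0 and 7 adjusted over the list alone; adjusted p = 2.8e-05, and adjusted p = 0.0293 with an estimated correlation), and S100a8 had 0.658 ± 0.231 FPKM against 22.8 ± 2.5. Of 24 non-CD8 T lineage genes with values, 8 passed the filter, and 5 of these were higher and 1 lower (5 and 2 adjusted over the list alone). As a list they moved up (camera adjusted p = 0.0382, but adjusted p = 0.333 with an estimated correlation). Besides Foxp3, Gata3, a T helper regulator, rose from 21.4 ± 0.38 to 88 ± 1.49, and Cxcr5 fell to 0.0935 ± 0.0778 from 6.36 ± 1.86. Without WT library 3, with a smaller pseudocount, no filter or array weights, or in genes without a GC-rich window this list was not called. Cd4, chosen after its values were seen, had 0.917 ± 0.0733 FPKM in DKO and 0.812 ± 0.0773 in WT.

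All 36 G2/M and mitosis genes fell (0 and 36 adjusted over the list alone), with a mean log2 fold change of -3.00 (adjusted p = 2.3e-31, and adjusted p = 0.00142 with an estimated correlation). Birc5 had 15.1 ± 2.26 FPKM against 246 ± 1.1, and Ccnb2 and Ccnb1, the B-type cyclins of mitosis, 8.34 ± 1.03 against 157 ± 3.74 and 4.11 ± 0.90 against 74.9 ± 6.64. Of 36 G1/S and S phase genes, 32 fell (0 and 33 adjusted over the list alone; adjusted p = 2.8e-22, and adjusted p = 0.00764 with an estimated correlation), Rrm2 to 22.4 ± 0.892 from 302 ± 17.7 FPKM. Replication-dependent histones had 1 higher and 5 lower of 17 (1 and 5 adjusted over the list alone; adjusted p = 0.0382, but adjusted p = 0.437 with an estimated correlation), a call lost with a mean of at least 5 FPKM, without DKO library 3 or WT library 3, or in genes without a GC-rich window. Cohesin and loop factors split 7 higher and 7 lower of 24 (9 and 8 adjusted over the list alone; adjusted p = 0.614, downward like the mean of -0.27, with a median of 0.08). Those that fell included Esco2 and Cdca5, which act on sister chromatids, and 8 members have a window of over 80% GC.

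Immediate early transcripts rose. Of 23 T cell receptor signalling and immediate early genes, 15 rose and 1 fell (15 and 2 adjusted over the list alone; adjusted p = 6.2e-06, and adjusted p = 0.0459 with an estimated correlation). Nr4a1, an orphan nuclear receptor induced by antigen receptor signals, rose from 21 ± 1.0 to 65.2 ± 4.46 FPKM and Nfkbia, an inhibitor of NF-κB, from 214 ± 4.04 to 473 ± 15.3; 5 members of the list have a window of over 80% GC. Of 25 homeostatic cytokine response genes, 12 rose and 6 fell (14 and 7 adjusted over the list alone; adjusted p = 0.120), with Cish, a feedback inhibitor of cytokine signalling, at 92.4 ± 7.88 FPKM against 16.3 ± 2.05 and Il6st, the shared receptor chain of the IL-6 family, at 12.2 ± 0.759 against 43.2 ± 1.56. Naive and quiescence genes split 15 higher and 11 lower of 30 (16 and 11 adjusted over the list alone; adjusted p = 0.601, upward like the median of 0.32, with a mean of -0.09). Igfbp4 fell from 217 ± 26.2 to 46.8 ± 1.37, and 9 members have a window of over 80% GC. T cell identity genes split 7 higher and 10 lower of 22 (8 and 11 adjusted over the list alone; adjusted p = 0.396), Cd247 at 765 ± 52.5 FPKM and Cd8a, the CD8 α chain, at 285 ± 7.0 against 447 ± 31.2. Trafficking receptors split 6 higher and 10 lower of 23 (6 and 10 adjusted over the list alone; adjusted p = 0.614). Itgae, the integrin chain CD103, rose from 84.1 ± 5.33 to 527 ± 17.3 and Cxcr6 from 80.6 ± 7.41 to 394 ± 18.4, while Cxcr3 fell to 19.5 ± 1.22. Inhibitory receptors and exhaustion genes split 6 and 5 of 16 (7 and 5 adjusted over the list alone; upward adjusted p = 0.800, with a median of -0.07 and a mean of -0.13); Cd160 fell to 12 ± 1.51 from 72.6 ± 4.59.

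Several metabolic lists also moved. Oxidative phosphorylation genes fell in 30 of 41 cases and rose in 0 (0 and 35 adjusted over the list alone; adjusted p = 3.2e-08, but adjusted p = 0.333 with an estimated correlation). Glycolysis genes rose in 3 and fell in 14 of 20 (3 and 14 adjusted over the list alone; adjusted p = 0.000535, but adjusted p = 0.290 with an estimated correlation), with Ldha, lactate dehydrogenase A, at 873 ± 47.2 FPKM against 1708 ± 117 and Tpi1, triosephosphate isomerase, at 63.5 ± 0.483 against 143 ± 9.88. Ribosome biogenesis genes fell in 18 of 39 cases (0 and 18 adjusted over the list alone; adjusted p = 0.00150, but adjusted p = 0.442 with an estimated correlation), and with the GC index as a covariate, or in genes without a GC-rich window, this list was not called. It has 0 members with a window of at least 80% GC, and the covariate can also take up an effect of the DKO genotype. The glycolysis call was also lost in genes without a GC-rich window. Cholesterol synthesis genes rose in 12 and fell in 1 of 23 (12 and 1 adjusted over the list alone; adjusted p = 0.000106, but adjusted p = 0.158 with an estimated correlation). Interferon-stimulated genes split 12 higher and 3 lower of 35 (12 and 3 adjusted over the list alone; adjusted p = 0.226), with Irf7 higher at 157 ± 9.02. p53 targets and apoptosis genes split 9 and 4 of 28 (9 and 4 adjusted over the list alone; adjusted p = 0.120), and Pmaip1, which encodes the apoptosis protein Noxa, rose from 5.95 ± 1.28 to 41.2 ± 6.72. Imprinted genes split 3 and 5 of 14 (3 and 5 adjusted over the list alone; adjusted p = 0.614).

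Of 16 B cell markers with values, 6 passed the filter, and in DKO 5 of these were higher and 1 lower (5 and 1 adjusted over the list alone). As a list they were called upward (camera adjusted p = 0.0332, but adjusted p = 0.290 with an estimated correlation), with a median of 0.47 and a mean of 0.07. The higher members besides Cd79b were the class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1. Cd79b had 109 ± 9.39 FPKM against 53 ± 1.69 and Cd74, the class II invariant chain, 399 ± 17.2 against 297 ± 9.43, while Cd22 fell to 0.392 ± 0.0507 from 6.53 ± 0.747; without WT library 3, with no filter or no intensity trend, or in genes without a GC-rich window this list was not called. Dendritic cell markers split 3 and 1 of 9 (3 and 1 adjusted over the list alone; adjusted p = 0.449). Erythroid markers split 3 and 1 of 9 (3 and 1 adjusted over the list alone; upward adjusted p = 0.614, with a median of -0.07 and a mean of -0.01). Macrophage and monocyte markers split 3 and 2 of 17 (1 and 2 adjusted over the list alone; upward adjusted p = 0.788 like the mean of 0.02, with a median of -0.05). Of the 2 tested members each of the untested lists, Pou2af1 of the plasma cell list fell to 0.059 ± 0.0672 from 6.45 ± 0.594, Pecam1 of the stroma list fell to 27.1 ± 0.859, and Itga2b of the platelet list rose to 1.41 ± 0.306 from 0.255 ± 0.198. Adjusted over the list alone, the platelet list had 2 higher.

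The largest rise after Foxp3 and Gzma was in Jund (82.9 ± 46.9 FPKM against 3.25 ± 4.13), followed by Fasl, Cdh1, which encodes E-cadherin (34.2 ± 3.92 against 1.06 ± 0.0963), Wnt5b, Taf10, Rnf187, Klf2 and Nrp1. Jund, Wnt5b, Taf10, Rnf187 and Klf2 each have a window of 82% GC or more. In the 1795 tested genes with a window of at least 80% GC the median log2 fold change was 0.49, and 35.2% were higher in DKO and 7.30% lower. In the 4234 genes with all windows under 70%, it was -0.09, with 12.8% higher and 27.5% lower. Taf10 and Rnf187 were no longer called with the GC index as a covariate. Among the largest falls, Rpl34-ps1, a ribosomal protein pseudogene on chromosome 3 whose midpoint lies 0.439 Mb from that of Lef1, had 7.38 ± 6.28 FPKM against 1271 ± 46.2. The others were Ly6c2, Klra13-ps, Dapl1, Ccnb2, Ube2c, Birc5, Ccnb1, the histone gene Hist1h2ao and S100a8. With the covariate, which can also take up an effect of the DKO genotype, the counts for DKO against WT were 975 higher and 1337 lower.

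**Figure D3:**
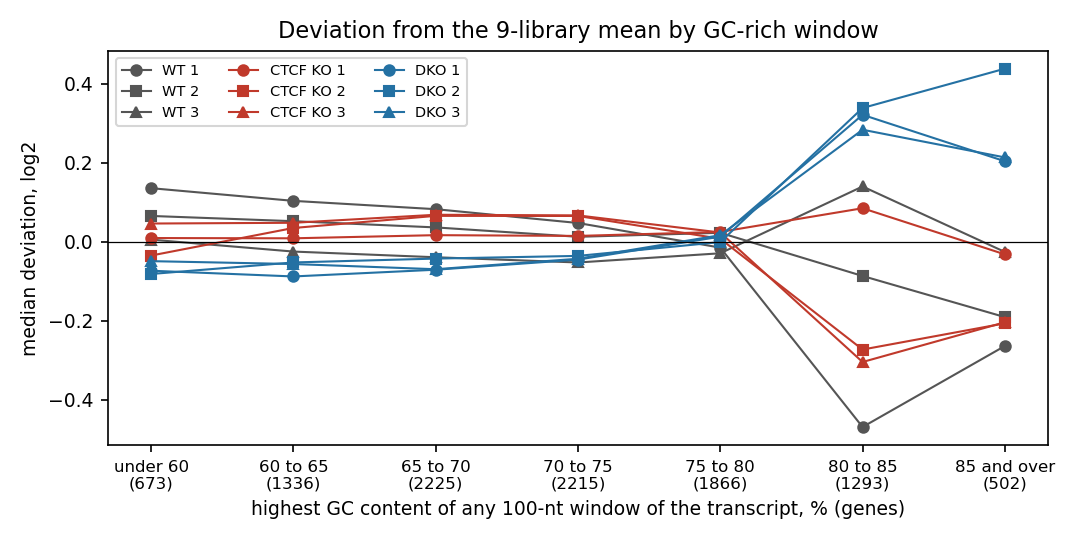
Median deviation of log2(FPKM + 1) from the mean of the 9 libraries, for tested genes grouped by the highest GC content of any 100-nt window of the transcript (horizontal axis, with the number of genes); each line is a library. In genes with a window of at least 80% GC the 3 DKO libraries lie highest, and CTCF KO library 1 and WT library 3 lie above the other libraries of their groups.

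To ask how the knockout groups differ from each other, the libraries labelled CTCF KO were compared with DKO. DKO libraries had more effector and immediate early transcripts, and fewer transcripts of the cell cycle, than the libraries labelled CTCF KO. Gzma, Fasl and Foxp3 had 9.07 ± 0.0659, 1.35 ± 0.139 and 0.94 ± 0.0236 FPKM in CTCF KO, and were lower than in DKO by log2 fold changes of -6.14, -5.84 and -5.83. Asns, asparagine synthetase, had 31.3 ± 1.27 FPKM in CTCF KO, 0.36 ± 0.232 in DKO and 16.5 ± 1.03 in WT. Of the 10172 genes, 2218 were higher in CTCF KO and 1649 lower (38.0%), with 1001 and 1038 at 1.5-fold or more and 454 and 586 at 2-fold or more; the groups did not overlap for 52.4%, where chance gives 10%. The authors' q-values under 0.05 marked 1377 genes higher and 1599 lower, and 2493 were called by both in the same direction and 0 in opposite directions. With the GC index as a covariate, which can also take up an effect of the DKO genotype, the counts were 1060 and 759. Y-linked transcripts were present in CTCF KO and near 0 in DKO, so donor sex and genotype cannot be told apart in this comparison.

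Cytotoxic effector genes were higher in CTCF KO in 4 and lower in 17 of 27 cases (4 and 17 adjusted over the list alone; adjusted p = 7.4e-07, and adjusted p = 0.00869 with an estimated correlation). G2/M and mitosis genes were higher in 35 of 36 (35 and 0 adjusted over the list alone; adjusted p = 2.3e-23, and adjusted p = 0.00331 with an estimated correlation), and G1/S and S phase genes in 32 of 36 (33 and 0 adjusted over the list alone; adjusted p = 9.6e-20, and adjusted p = 0.00869 with an estimated correlation). T cell receptor signalling and immediate early genes were higher in 1 and lower in 18 of 23 (2 and 18 adjusted over the list alone; adjusted p = 1.0e-08, and adjusted p = 0.0163 with an estimated correlation). The other called lists lost their call with an estimated correlation. Interferon-stimulated genes were higher in 1 and lower in 17 of 35 (1 and 17 adjusted over the list alone; adjusted p = 9.0e-05, but adjusted p = 0.216 with an estimated correlation). Glycolysis genes were higher in 14 and lower in 1 of 20 (14 and 1 adjusted over the list alone; adjusted p = 8.4e-05, but adjusted p = 0.216 with an estimated correlation). Oxidative phosphorylation genes were higher in 23 of 41 (26 and 0 adjusted over the list alone; adjusted p = 3.0e-05, but adjusted p = 0.456 with an estimated correlation) and ribosome biogenesis genes in 19 of 39 (19 and 0 adjusted over the list alone; adjusted p = 0.000293, but adjusted p = 0.384 with an estimated correlation). Neither of these was called with the GC index as a covariate.

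Cholesterol synthesis genes were higher in 1 and lower in 9 of 23 (1 and 9 adjusted over the list alone; adjusted p = 0.00299, but adjusted p = 0.216 with an estimated correlation). T cell identity genes were higher in 13 and lower in 4 of 22 (13 and 4 adjusted over the list alone; adjusted p = 0.0204, but adjusted p = 0.490 with an estimated correlation). Non-CD8 T lineage genes were higher in 3 and lower in 5 of 8 (3 and 5 adjusted over the list alone; adjusted p = 0.0214, but adjusted p = 0.269 with an estimated correlation). B cell markers were higher in 1 and lower in 5 of 6 (1 and 5 adjusted over the list alone; adjusted p = 0.00356, but adjusted p = 0.210 with an estimated correlation). In genes without a GC-rich window the cholesterol synthesis, glycolysis and non-CD8 T lineage lists lost their call, and the T cell identity call was lost with quantile normalization or with the GC index as a covariate. The 14 other lists tested were not called, with adjusted p from 0.0619 for neutrophil markers to 0.830 for macrophage and monocyte markers. In 6 of these the median and the mean had different signs: cohesin and loop factors, inhibitory receptors and exhaustion, naive and quiescence, p53 targets and apoptosis, trafficking receptors and the targeted genes.

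**Figure D4:**
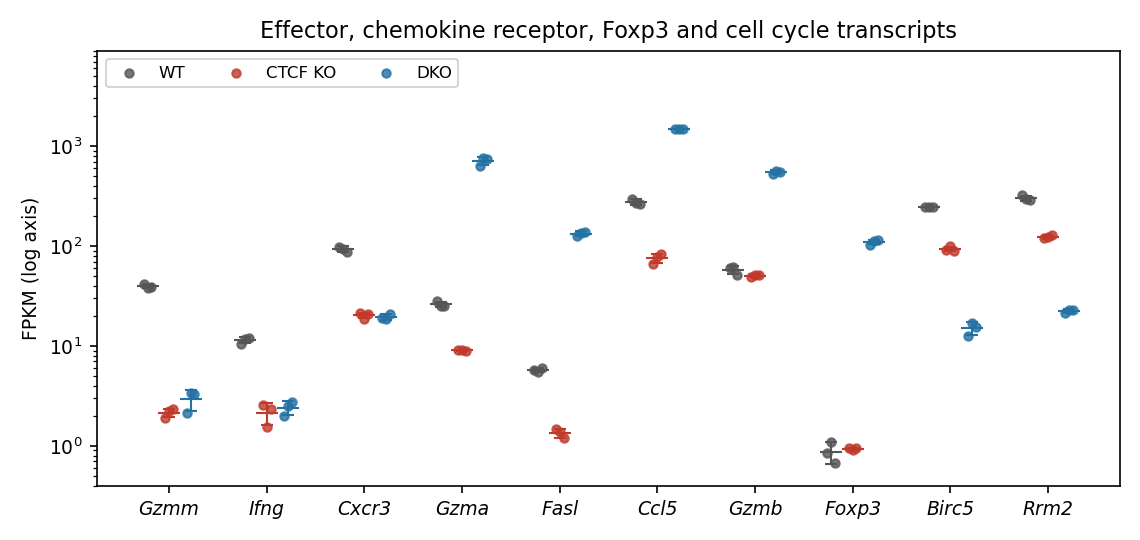
FPKM on a log axis of effector genes, the chemokine receptor Cxcr3, Foxp3 and the cell cycle genes Birc5 and Rrm2 in the libraries of WT, CTCF KO and DKO (points), with means (horizontal bars) and SD (error bars) of 3 libraries. Gzma has a mean of 9.07 FPKM in CTCF KO, 26.0 in WT and 709 in DKO, and Birc5 93.6, 246 and 15.1.

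To ask how far the knockouts share their differences from WT, both were compared gene by gene. Higher in both were 261 genes, where independent lists give 109. Lower in both were 479, where independent lists give 142. The 5 named genes lower in both were Klra13-ps, Gzmm, Samd3, Ngp and Klre1, and those higher in both were Ppm1n, Xlr, Wnt5b, Prss2 and Apol9b. The CTCF KO calls of Ppm1n, Xlr and Wnt5b were each lost in at least 1 alternative, and so was the DKO call of Xlr. The others named here kept both calls in every alternative that tested them. Across the 10172 genes, which are not independent replicates, the log2 fold changes of both knockouts had a Pearson r of 0.30 and a Spearman rho of 0.29. In 100 simulations of shared WT libraries with no effect, the mean r was 0.48 (highest 0.93), rho 0.45 (highest 0.89) and covariance 0.0287 (highest 0.105). The observed covariance was 0.0879, and none of these 3 observed measures lay above the highest simulated. They cannot show whether effects are shared, because shared WT libraries alone raise r and unrelated effects lower it. The highest simulated count of genes called in both was 0 in either direction. With no effect simulated, this does not measure sharing either. The 3 WT libraries serve both comparisons and are too few to be split into separate controls, so the part of the excess overlap that they add was not separated. Opposite calls were fewer than independent lists give: 73 genes were higher in CTCF KO and lower in DKO (129 for independent lists), among them Asns, Igfbp4 and Il6st, and 51 lower in CTCF KO and higher in DKO (120 for independent lists), among them Gzma, Fasl and Ccl5. Without CTCF KO library 1 the correlation was 0.16, and without WT library 3 it was 0.48; the shared counts went down by over 1.5 times without CTCF KO library 2 or 3 or WT library 2 or 3 (higher in both: 159, 165, 150 and 168) and without WT library 2 (lower in both: 300).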

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

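The tests of explanations for the 3 patterns weighed below, and the alternatives that use the GC index, leave out genes with a GC-rich window or leave out CTCF KO library 1 with WT library 3, were chosen after the results they address had been seen. The results below are here because the effects of the knockout groups against the same WT libraries differed by a limma test of the difference. For genes with opposite calls against WT, this test adds no separate support. The standard error of a gene is the same in each comparison, and the difference is larger than either effect. All 124 opposite calls passed it.

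Opposite calls were made for 51 genes lower in CTCF KO and higher in DKO than WT, and for 73 genes higher in CTCF KO and lower in DKO. As above, directions are those of the libraries labelled CTCF KO, whose Y-linked transcripts set them apart from WT and DKO alike (weighed below). Effector and signalling genes lower in CTCF KO and higher in DKO had log2 fold changes, CTCF KO minus DKO, of -6.14 for Gzma, -5.84 for Fasl, -4.27 for Ccl5, -1.34 for Tnfaip3, -1.39 for Nfkbia and -1.17 for Junb. The same direction was seen for the regulator Gata3 (-2.38), the growth regulator Slfn2 (-1.54), the interferon-induced Bst2 (-1.08) and the B cell marker Cd79b (-1.61). Genes higher in CTCF KO and lower in DKO had differences of 4.58 for Asns, 3.02 for Igfbp4, 2.24 for Lef1, 2.11 for Il6st, 1.24 for Cd5, 1.12 for Ccr7, the lymph node homing receptor, and 0.58 for Pecam1. The Y-linked Eif2s3y differed by 5.31, and its DKO libraries were lower than WT at 0.136 ± 0.0937 against 0.839 ± 0.525 FPKM. Of these genes, only Gzma, Fasl, Ccl5, Slfn2 and Igfbp4 kept both calls against WT in every alternative that tested them. The CTCF KO call was lost in 11 of 19 alternatives for Pecam1 and for Ccr7, and in 1 to 3 for Lef1, Cd5, Junb, Nfkbia, Bst2, Cd79b, Gata3, Il6st and Asns. The DKO call was lost in 8 of 18 for Eif2s3y and in 2 each for Tnfaip3 and Pecam1, and 0 calls turned direction. As a list, T cell receptor signalling and immediate early genes had a mean difference of -1.12.

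The first pattern weighed is that Ctcf RNA was not called lower in the libraries labelled CTCF KO. That poor recovery of GC-rich windows in some WT libraries hid a log2 fold change of -1 or lower is argued against: with the GC index as a covariate it was -0.31 (SE 0.11, 95% interval -0.55 to -0.07), against -0.33 (SE 0.19, -0.74 to 0.09) without it. A smaller loss hidden in this way stays open, since the interval with the covariate lies below 0 while its limma adjusted p of 0.0789 (0.319 without the covariate) misses the threshold. In the summed FPKM of Y-linked genes, 0 of the 6 libraries lay on the other group's side. This argues against an exchange of single libraries with WT only if the donors of each group were of 1 sex, which the labels do not give. An exchange of the whole groups would not show in this measure. RNA from outside the deleted part of Ctcf, or from cells that kept the gene, may account for a mean of 0.767 of the WT mean, but cannot be told apart from intact alleles here, because values per exon were not used.

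The second pattern is that genes with a GC-rich window were higher in the DKO libraries. A candidate explanation is that libraries differ in how well such windows are recovered, since the same genes differ between libraries of 1 genotype: across the 1795 genes with a window of at least 80% GC, the deviation of CTCF KO library 1 from libraries 2 and 3 had an r of 0.528 with DKO minus WT, and 0.0113 in the 4234 genes under 70%. The deviation of WT library 3 from WT libraries 1 and 2 had an r of 0.887 with that of CTCF KO library 1 in the first genes and -0.0228 in the second. An effect of the DKO genotype on these genes stays open: with the index as a covariate 138 of the 1795 were called higher (136 of them also without it) and 283 lower, against 631 and 131 without it. Genotype and recovery cannot be told apart for them, because the lowest index of a DKO library (0.324) lies above the highest of the other libraries (0.127).

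The third pattern is that Y-linked transcripts were present in every library labelled CTCF KO and near 0 in the others. The mean Xist FPKM was 0.161% of the WT mean, below a bound of 10%. This argues against male cells mixed into a sample of female cells, provided that the genotype does not itself lower Xist, which was not tested. The values are consistent with male donors for this group and female donors for both others, since the highest Xist FPKM was 0.00696 in CTCF KO and the lowest elsewhere 1.71. For the 1197 autosomal genes called in CTCF KO against WT, donor sex and genotype cannot be told apart, because no library labelled CTCF KO lacks the Y-linked transcripts. The same holds for the 3751 autosomal genes called in CTCF KO against DKO. On X and Y, 39 of 320 tested genes were called in CTCF KO against WT (12.2%), and 12.2% of autosomal genes.

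The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, so no share under 0.05 can be reached. In CTCF KO against WT, 1 of the 10 splits, the real one, gave 1236 called genes and the highest other gave 366; that other split put CTCF KO library 1 with WT libraries 2 and 3, the libraries of the 6 with the highest GC index. In DKO against WT the real split gave 4113 genes and the highest other 0, and in CTCF KO against DKO 3867 and 0.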

How the results depend on the processing

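Results for leaving out CTCF KO library 1 with WT library 3, for genes with no GC-rich window and for the GC covariate come from settings chosen after the data had been seen. Of 22 alternatives set beforehand and 3 added, calls opposite in direction to those reported occurred in 1 gene, in DKO against WT with the covariate. Of the named genes called, 51 of 101 (CTCF KO against WT), 100 of 121 (DKO against WT) and 79 of 108 (CTCF KO against DKO) stayed called in every alternative that tested them, and 0 turned direction while called.

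Requiring 1.5-fold left 249 higher and 358 lower, 1054 and 1035, and 1001 and 1038 in these comparisons, and 80 higher and 241 lower in both knockouts, by construction. Array weights gave 1147 and 1132 for CTCF KO against WT and 537 and 793 for both knockouts. A common library median gave 148 higher in both. Leaving out a replicate gave 343 to 481 higher and 411 to 572 lower for CTCF KO against WT, 150 to 217 higher and 300 to 454 lower in both knockouts, and correlations of 0.16 to 0.48. Without CTCF KO library 1 and WT library 3, 337 were higher in CTCF KO against WT and 148 and 319 shared. Only the 4234 genes with no GC-rich window, fewer by construction, gave 313 higher in CTCF KO against WT, 558 and 1223 in DKO against WT, 1180 and 508 in CTCF KO against DKO, 113 and 311 shared, and a correlation of 0.43. The covariate gave 975 and 1337 in DKO against WT, 1060 and 759 in CTCF KO against DKO, and a correlation of 0.40. In genes with no GC-rich window 8 of 11 lists called in CTCF KO against WT, 6 of 11 in DKO against WT and 9 of 12 in CTCF KO against DKO kept their call. With a mean of at least 5 FPKM, 8 of 11, 9 of 11 and 12 of 12 kept it. List calls with an estimated correlation were 3, 4 and 4, and with fry, which does not compare a list with other genes, 23 in DKO against WT and 20 in CTCF KO against DKO. Beyond the settings whose construction is named, the cause was not tested.

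Pou2af1 in CTCF KO against WT, not called, ranged from -0.29 to 0.042 over left-out replicates (0.042 without CTCF KO library 1) and was 0.039 without CTCF KO library 1 and WT library 3, against -0.16. The T cell receptor signalling and immediate early list in CTCF KO against WT turned up in genes with no GC-rich window (adjusted p = 0.880; over its alternatives 0.000997 to 0.880).

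A block on the replicate number, fitted to only the CTCF KO and WT libraries, gave 95 higher and 202 lower in CTCF KO against WT; these 6 libraries without the block gave 436 and 545. Libraries with the same number deviated from their groups with r of -0.62, 0.16 and -0.45, so a shared number did not go with like deviations. This cannot exclude a pairing, because such libraries also differ in the GC index. It was 0.043 in CTCF KO and -0.484 in WT for number 1, and -0.322 and 0.127 for number 3. No paired analysis was possible for the DKO comparisons, because their columns carry only a group. Tests on counts were not run, as the table holds no counts, and a minimum fold has no meaning for lists. The FPKM values give no depth, so it is not known what depth limits.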

Other observations

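The tests of flanking genes and of neighbouring genes in this part were chosen after the results had been seen.

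Some differences of the libraries labelled CTCF KO lay next to each other on the genome. Ifng and the long non-coding RNA gene beside it, Tmevpg1, which was chosen after its values were seen, had log2 fold changes of -1.99 and -1.93 against WT. The fall of Ifng was not particular to this group: its mean FPKM was 0.188 of the WT mean in CTCF KO and 0.211 in DKO. A hypothesis is that loss of CTCF, which insulates neighbouring genes, may change neighbours together. Pairs of adjacent tested autosomal genes within 100 kb were counted, leaving out those whose names were alike up to a final number. Some pairs of related genes stayed in. Among these 6365 pairs, 100 had the same call, where permuted calls gave a mean of 47.0 (permutation p = 1e-04, the smallest that 10000 permutations can give). The same number of genes with the smallest p in DKO against WT gave 82 pairs, where permuted calls gave 46.9 (permutation p = 1e-04, again the smallest possible). The difference of 18 pairs had a permutation p over 19 chromosomes of 0.201, so the data leave open whether neighbours move together more in CTCF KO than in DKO.

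Donor DNA that flanks a deleted gene may carry other alleles. Within 5 Mb of Lef1 or Tcf7, 47 of 91 tested genes were called in DKO against WT (51.6%), and 4064 of 10079 elsewhere (40.3%). The odds ratio was 1.58 (Fisher's exact test, p = 0.0317, adjusted over both such tests 0.0635), which leaves this open for DKO. Within 5 Mb of Ctcf, 5 of 70 were called in CTCF KO against WT (7.14%) and 1231 of 10101 elsewhere (12.2%), an odds ratio of 0.554 (Fisher's exact test, p = 0.269), so called genes did not gather there.

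Pancreatic transcripts outside the named set, chosen after their values were seen, were low: Cpa1 had 0.998 ± 0.17 FPKM in CTCF KO, 0.258 ± 0.0634 in DKO and was listed at 0 in WT, and Try4 had 2.04 ± 0.468, 0.351 ± 0.272 and 0. Prss2, a trypsinogen gene within the T cell receptor β locus, had 6.99 ± 0.633, 3.73 ± 0.348 and 1.12 ± 0.595.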
